A study of Mus musculus with 10 samples.

How the data were processed

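RNA from mouse trophoblast stem (TS) cells and their derivatives was hybridised to 10 dual-colour Agilent arrays on 4 slides, each slide with 4 array positions. Every array carried RNA of undifferentiated wild-type TS cells, TS(WT), in Cy3 and the test RNA in Cy5, so there was 1 dye orientation and no dye swap. The test groups were T(Diff), 3 samples taken after 4 days of differentiation, and T(Inv), 3 samples of cells of the same age recovered after they had passed through Matrigel. The last group was TS(KI4), TS cells in which the kinase MAP3K4 is inactive, with 2 biological samples on 2 duplicate arrays each. An array named without a replicate number was taken as the duplicate of TS(KI4) sample 1, by elimination and because both lay on the same slide. The agreement of the arrays, given in the results, does not settle this. The duplicate arrays of each TS(KI4) sample were averaged before any test.

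The values used were the log2 ratios of test over wild-type RNA that the authors deposited, 1 per feature and array. The log base and the direction were read from the values and from the dye labels: the largest value, 14.8, lies below the 16 that a ratio of 16-bit intensities can reach in log2 and above what natural or decimal logarithms allow. How the authors corrected background, normalised and filtered the values, and how they scaled them between arrays, is not given in the sources used here. The deposited array medians lay between 0 and 0.021 log2. No value was missing. The deposited tables hold no intensities, so features near background could not be left out, and the number of arrays limits the precision.

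Of 45220 features, 33709 carried a gene annotation from the platform and 11511 did not. Among the annotated features, 56 named several symbols and 33653 named 1 symbol. The latter gave 19087 genes, 10744 with 1 feature and 8343 with several, whose features were averaged. For 33517 features the symbol was found in the gene table of the mouse genome build GRCm38.p6, which was used for current symbols, chromosomes and gene order. The marker genes Prl3d1 and Prl2c2 are not analysed here because no feature names either of them alone. Probes of near-identical families (Prl, Psg, Serpinb9 and Ifit genes) can bind more than 1 member, so the values of single members are uncertain.

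The test was limma (lmFit and eBayes, version 3.58.1, in R 4.3.3) on the log2 ratios per gene, with all 3 groups in the same fit. This left 5 residual degrees of freedom, to which the moderation added 2.71, with a prior spread of 0.227 log2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and the number at least 2-fold changed is given beside the calls. A comparison with TS(WT) tests the mean log2 ratio against 0. The wild-type RNA thus counts as 1 control sample, and neither its own spread nor a dye effect is in the error. Comparisons between test groups are differences of the mean log2 ratios, in which a constant dye effect cancels. The reference cancels as well if all slides carried the same wild-type RNA, which is not known. TS(KI4) shared no slide with T(Diff) or T(Inv), so its differences from them cannot be separated from those of slide or reference RNA.

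Shifts of 30 gene lists (624 genes listed, 578 measured) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The alternatives were camera with an estimated correlation and fry. With an estimated correlation camera rests on the 5 residual degrees of freedom and has little power after adjustment over 30 lists. A call lost there does not show that correlation between genes produced it. At the preset, however, p-values may be too small for lists whose estimated correlation lay well above 0.01. The lists came from general knowledge of trophoblast, epithelial-mesenchymal transition (EMT) and culture conditions. Listed symbols that were absent were looked up by their synonyms. Overlaps of calls are given beside the number for independent lists and the mean of 20 simulations of unchanged groups that share 1 reference sample.

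Genes are named by a rule. In each comparison with TS(WT) and in T(Inv) against T(Diff), these were the 6 highest and the 6 lowest called genes whose samples all had the same sign, or whose groups did not overlap. Clone names and predicted genes were left out. For each list described, up to 4 called members with the largest change could be named, or up to 2 members where no member was called. Map3k4, Crebbp, Ep300, Hdac6, Cdh1, Vim, Snai1, Snai2, Cdx2 and Eomes were named in every comparison. The groups, the test, the lists, the naming rule and the alternatives below were chosen before the data were examined.

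The alternatives were centring each array on its median, quantile normalization between arrays, the feature with the largest variance in place of the mean of features, a fit of only the groups compared, and the duplicate arrays as a random block. Further alternatives were slide as a random or a fixed block, the replicate number as a block, a robust moderation, limma's treat against a 1.2-fold change, and each sample left out in turn. Chosen after the data were seen were fits without genes of chromosomes 1, 2, 8, X and Y and fits of only those genes whose features all had the same sign. Quantile normalization gives all arrays the same distribution. It thus widens the ratios of TS(KI4), whose arrays had SDs of 0.659 to 0.731. It narrows those of T(Diff) and T(Inv), whose arrays had SDs of 0.996 to 1.21.

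The code was tested on simulated data with the real samples' spread for 19087 genes. With 200 genes changed in a comparison with TS(WT), limma called 8.96% of those changed by 0.5 log2 in T(Diff), 44.8% of those changed by 1 and 89.4% of those changed by 2. The shares were 8.96%, 58.2% and 90.9% in T(Inv) and 4.48%, 52.2% and 81.8% in TS(KI4). In T(Inv) against T(Diff), with 400 genes changed, they were 2.24%, 32.8% and 84.1%. Unchanged genes called numbered 4, 8, 6 and 9 in these comparisons. These data held no reference sample, so the counts leave out the false calls that its spread adds in comparisons with TS(WT). In the simulations with 1 shared reference sample, unchanged T(Diff) and T(Inv) had a mean of 831 shared calls in the same direction.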

Results

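The data are log2 ratios of gene expression in 8 biological samples of mouse trophoblast cells, measured on 10 arrays of 45220 features and summarised to 19087 genes. Trophoblast stem (TS) cells are the self-renewing cells of the early placental lineage, which FGF signalling keeps undifferentiated. The groups were T(Diff), 3 samples taken after 4 days of differentiation, T(Inv), 3 samples of such cells recovered after invading Matrigel, and TS(KI4), 2 samples of undifferentiated TS cells with inactive MAP3K4. Each was set against RNA of undifferentiated wild-type TS cells, TS(WT), on the same array. MAP3K4 is a kinase upstream of the stress-activated MAP kinases. Correlations between arrays of different samples, across features, ranged from 0.753 to 0.844 in T(Diff), from 0.827 to 0.863 in T(Inv) and from 0.593 to 0.607 in TS(KI4). Duplicate arrays correlated at 0.635 in TS(KI4) sample 1, which includes the array named without a replicate number, and at 0.815 in sample 2. The SD of their difference was 0.623 in sample 1 and 0.418 in sample 2, against 0.617 to 0.647 between arrays of different TS(KI4) samples. By this measure the arrays of sample 1 differed as much as arrays of different samples, so their assignment rests on the names and the slide. T(Diff) sample 2 had the widest spread of log2 ratios, with an SD of 1.21 against 0.659 to 1.10 on the other arrays. All T(Diff) samples and T(Inv) sample 3 shared slide 1, T(Inv) samples 1 and 2 lay on slide 2, and each TS(KI4) sample had its own slide. The labels do not say whether the T(Diff) and T(Inv) samples came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. Values are mean log2 changes ± SD over samples, p-values are limma's adjusted p, and list members count as changed when adjusted over all genes. A count adjusted over the list alone is given where it differs from that count.

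The comparison of T(Diff) with TS(WT) asks which genes change as TS cells differentiate. FGF and ERK target genes lay far below their level in TS cells, and genes of trophoblast giant cells, of the labyrinth and of the interferon response lay above it. These list calls were lost with an estimated correlation (lowest adjusted p = 0.543), a setting with 5 residual degrees of freedom and little power. Sox2, a transcription factor of TS cell self-renewal, fell by 6.27 ± 0.14 (n = 3, adjusted p 4.92e-07). Cdx2, which specifies the trophoblast lineage, fell by 2.56 ± 0.19, Elf5 fell by 2.35 ± 0.04 and Bmp4 fell by 2.50 ± 0.07. Eomes, another TS cell factor, rose by 0.74 ± 0.18 (adjusted p 9.92e-04). In the list of 16 TS cell genes, 9 fell, 3 rose (4 when adjusted over the list alone) and the list as a whole was not shifted beyond other genes (median -0.95, camera adjusted p 0.113). Of 15 FGF and ERK feedback targets, 14 fell (median -2.27, camera adjusted p 8.45e-06, adjusted p = 0.577 with an estimated correlation). Among them Dusp6, a phosphatase that restrains ERK, fell by 6.45 ± 0.17, the immediate early factor Egr1 fell by 4.30 ± 0.22 and the FGF antagonist Spry1 fell by 3.25 ± 0.11.

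Of 18 giant cell genes, 12 rose and 2 fell, or 3 fell when adjusted over the list alone (median 1.22, camera adjusted p 0.0029, adjusted p = 0.543 with an estimated correlation). The placental hormone gene Prl7a1 rose by 4.35 ± 0.17 and its relative Prl2a1 rose by 3.68 ± 0.48. Of 14 labyrinth and syncytiotrophoblast genes, 11 rose and 3 did not pass (median 1.47, camera adjusted p 9.64e-05, adjusted p = 0.543 with an estimated correlation), among them the transcription factors Dlx3 at 2.72 ± 0.22 and Cebpa at 2.53. Of 24 interferon response genes, 18 rose and 1 fell, or 19 rose when adjusted over the list alone (median 2.27, camera adjusted p 6.08e-08, adjusted p = 0.543 with an estimated correlation). Rtp4, an interferon-induced chaperone of receptors, had the highest change of the genes named, 6.22 ± 0.10 or 74.4-fold, followed by the placental kinase Nrk at 5.42 ± 0.09 and the antiviral gene Ifit1 at 5.22 ± 0.35. Peg10, an imprinted gene needed for placental growth, rose by 4.80 ± 0.40. In the list of 22 imprinted genes 13 rose and 2 fell (median 0.43, camera adjusted p 0.0369, adjusted p = 0.579 with an estimated correlation), a call that was lost without T(Diff) sample 2 (adjusted p 0.0608). Of 18 cholesterol synthesis genes, 11 fell and 1 rose (median -1.01, camera adjusted p 0.0131, adjusted p = 0.625 with an estimated correlation), with Msmo1, a sterol oxidase, down by a log2 change of -2.21 ± 0.28. Gdf6, a ligand of the BMP family, fell by 7.05 ± 0.76 and the membrane protein gene Bves fell by 6.72 ± 0.25. The adhesion gene Ceacam12 was called at 4.75 ± 4.31, with 9.73 in sample 2 against 2.13 and 2.39 in the others, and was not called with only the groups compared (adjusted p 0.0791).

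Epithelial genes did not fall as a group in T(Diff). Of 34 epithelial junction and identity genes, 24 rose and 4 fell, or 25 rose when adjusted over the list alone (median 0.74, camera adjusted p 9.64e-05, adjusted p = 0.579 with an estimated correlation). The keratin genes Krt19 and Krt8 rose by 3.27 ± 0.29 and 2.26 ± 0.26. Cdh1, which encodes E-cadherin, was at -0.41 ± 0.33 (adjusted p 0.0415), a call that was lost when T(Diff) sample 1 or 3 was left out (-0.28 and -0.35). The EMT factor Snai1 rose by 1.70 ± 0.14, whereas its relative Snai2 fell by 2.06 ± 0.27. Of 14 EMT transcription factors, 5 rose and 4 fell (median 0.03, camera adjusted p 0.708). Of 30 mesenchymal genes, 8 rose (7 when adjusted over the list alone) and 5 fell (median 0.15, camera adjusted p 0.601). The mesenchymal filament gene Vim was at -0.53 ± 0.45 and not called (adjusted p 0.0618), and its 2 features differed in sign, 0.46 and -1.51. Of 28 mitotic genes, 16 fell and 2 rose, without a call for the list (median -0.57, camera adjusted p 0.0547). Map3k4 was at 0.24 ± 0.19 (adjusted p 0.126), with features from -0.60 to 1.63. Transcripts of the histone acetyltransferases Crebbp and Ep300 rose by 0.41 ± 0.41 (adjusted p 0.0473) and 0.58 ± 0.19 (adjusted p 0.00569), and the deacetylase gene Hdac6 rose by 0.53 ± 0.09 (adjusted p 0.0275). Crebbp lost its call without T(Diff) sample 2 (0.23) or 3 (0.37), and Hdac6 without any of samples 1, 2 and 3 (0.48 to 0.56). Cdh1, Crebbp and Hdac6 also lost theirs after quantile normalization (-0.34, 0.33 and 0.43), with slide as a random block (adjusted p 0.0952, 0.067 and 0.0534) and with treat (0.312, 0.324 and 0.161), and Ep300 with treat (0.0507). Cdh1 and Crebbp lost theirs with only the groups compared (adjusted p 0.107 and 0.143), Cdh1 with the feature of largest variance (0.0658) and Crebbp after centring (0.0528). With the feature of largest variance, Vim at -1.51 (adjusted p 8.14e-05) and Map3k4 at 1.63 (adjusted p 0.00204) were called.

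In all, limma called 10458 genes in T(Diff), 5078 higher and 5380 lower, of which 1975 and 2506 changed at least 2-fold. In 1269 of the 8343 genes with several features, features were called in opposite directions. The wild-type RNA is a single control whose own spread is not in the error.

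The comparison of T(Inv) with TS(WT) asks the same of the cells that had invaded Matrigel. The main changes of T(Diff) were present, and mitotic genes were lower as a group. No list call was kept with an estimated correlation (lowest adjusted p = 0.463). Sox2 fell by 6.03 ± 0.22 (n = 3, adjusted p 4.62e-07), Cdx2 fell by 2.16 ± 0.14 and Dusp6 fell by 5.71 ± 0.16, while Eomes rose by 0.56 ± 0.19 (adjusted p 0.00438). Rtp4 rose by 6.08 ± 0.23, the small GTPase gene Rhob rose by 5.24 ± 0.26, Prl7a1 rose by 4.79 ± 0.31 and the interferon-inducible Ifi202b rose by 4.60 ± 0.46. Of 28 mitotic genes, 20 fell and 1 rose (median -0.80, camera adjusted p 1.32e-04, adjusted p = 0.528 with an estimated correlation), among them the centromere gene Cenpf at -2.54 ± 0.43 and the kinase gene Aurkb at -2.13 ± 0.06. Of 28 DNA replication genes, 16 fell and 5 rose (median -0.43, camera adjusted p 0.0355, adjusted p = 0.528 with an estimated correlation), a call that the feature of largest variance per gene did not give (median -0.40). Of 15 FGF and ERK targets, 13 fell and 1 rose (median -1.99, camera adjusted p 1.32e-04, adjusted p = 0.528 with an estimated correlation). The cholesterol synthesis list had 13 of 18 genes lower and 1 higher, or 14 lower when adjusted over the list alone (median -0.82, camera adjusted p 0.00413, adjusted p = 0.743 with an estimated correlation).

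Giant cell genes were higher in T(Inv), with 11 of 18 up and 2 down (median 1.77, camera adjusted p 0.00182, adjusted p = 0.463 with an estimated correlation). So were labyrinth genes, with 8 of 14 up and 1 down (median 0.71, camera adjusted p 0.00841, adjusted p = 0.528 with an estimated correlation). Interferon response genes had 18 of 24 up and 2 down (median 2.09, camera adjusted p 9.71e-07, adjusted p = 0.463 with an estimated correlation). Epithelial genes had 19 of 34 up and 7 down, or 20 up when adjusted over the list alone (median 0.54, camera adjusted p 0.00841, adjusted p = 0.743 with an estimated correlation). Krt19 rose by 3.76 ± 0.36, whereas Cdh1 fell by 1.33 ± 0.23 (adjusted p 1.07e-04). Snai1 rose by 1.63 ± 0.12 and Snai2 fell by 1.89 ± 1.52 (adjusted p 0.00929). Of the 14 EMT factors 6 rose and 2 fell (median 0.15, camera adjusted p 0.327), and of the 30 mesenchymal genes 7 rose (6 when adjusted over the list alone) and 6 fell (median 0.14, camera adjusted p 0.691). Vim fell by 0.61 ± 0.30 (adjusted p 0.0357). The call of Snai2 was lost without T(Inv) sample 3 (-1.74), and that of Vim without sample 1 (-0.47) or 2 (-0.59). Snai2 was also not called with only the groups compared (adjusted p 0.0693). Vim was also not called with duplicate arrays (adjusted p 0.267) or slide (0.13) as a random block, after quantile normalization (0.0796) or with treat (0.143). Map3k4 fell by 0.55 ± 0.25 (adjusted p 0.00524), with features from -1.18 to -0.09, and was not called with the feature of largest variance (-0.09, adjusted p 0.824) or with treat (adjusted p 0.0576). Ep300 rose by 0.67 ± 0.27 (adjusted p 0.00282), and Crebbp at -0.06 ± 0.07 (adjusted p 0.779) and Hdac6 at 0.41 ± 0.10 (adjusted p 0.0705, or 0.0171 with only the groups compared) were not called. limma called 10249 genes, 4984 higher and 5265 lower, of which 1955 and 2445 changed at least 2-fold, and in 1367 genes features were called in opposite directions.

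T(Diff) and T(Inv) changed largely the same genes, with 3960 genes higher in both, 4381 lower in both and 65 called in opposite directions. Independent lists of these sizes would share 1326 higher and 1484 lower genes, and unchanged groups with a shared reference shared 831 calls of the same direction. Across genes, which are not independent replicates, the changes correlated at 0.901 (simulated 0.751) with a covariance of 0.825 (simulated 0.107). The covariance above the simulated value was 0.718. The single reference could not be split, so part of the excess overlap may come from it.

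**Figure D1:**
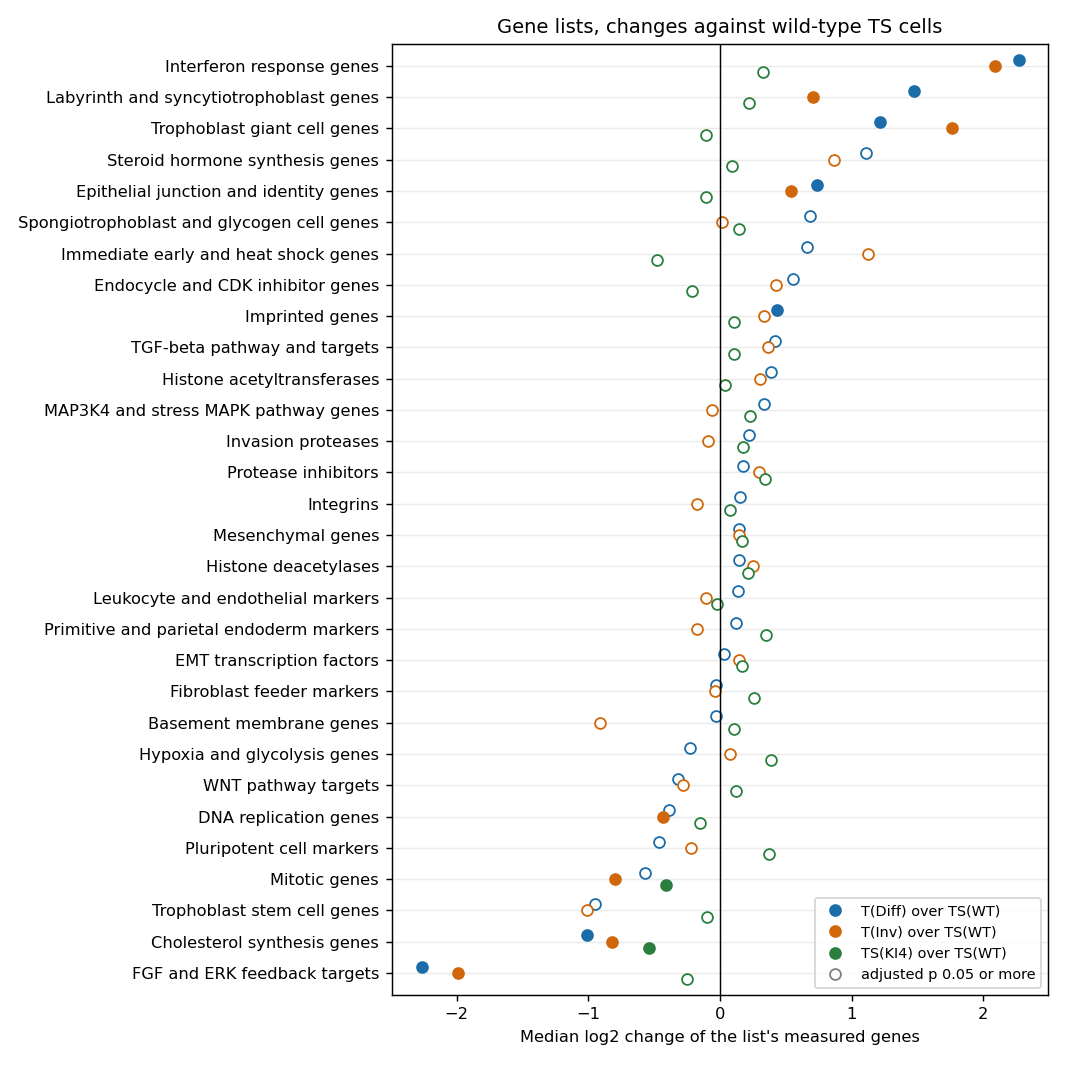
Median log2 change of each gene list (horizontal axis, log2 units) in T(Diff), T(Inv) and TS(KI4) against TS(WT), with the lists called by camera marked. FGF and ERK feedback targets lie at -2.27 in T(Diff) and -1.99 in T(Inv), and interferon response genes at 2.27 and 2.09.

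The comparison of T(Inv) with T(Diff) asks which genes distinguish invading cells from differentiated cells that were not selected by invasion. T(Inv) cells had also passed through Matrigel and been recovered. Traits of invading cells thus cannot be separated from effects of the matrix or of the recovery. Invading cells had more RNA of Thbd, Emp1 and Ccn2 and less of Epha4, and their basement membrane and mitotic genes lay lower as groups. The list calls were lost with an estimated correlation (adjusted p = 0.763 for each of the 6 lists below), and fry called 0 lists. Thbd, the anticoagulant receptor thrombomodulin, was higher by 2.40 ± 0.14 (SE, 3 samples a group, adjusted p 0.00333), at 3.39 ± 0.09 in T(Inv) and 0.98 ± 0.17 in T(Diff). Emp1, a membrane protein gene, went from -1.52 ± 0.72 to 1.79 ± 0.21 (adjusted p 0.034), and Ccn2, which encodes connective tissue growth factor, went from -2.03 ± 0.74 to 0.96 ± 0.12 (adjusted p 0.034). Epha4, a receptor of ephrins, was lower, at 0.16 ± 0.26 against 2.83 ± 0.39 (adjusted p 0.0277), and the receptor gene Notch3 was lower at -1.72 (adjusted p 0.047). Of 16 basement membrane genes 1 fell, or 7 when adjusted over the list alone (median -0.68, camera adjusted p 1.41e-05). The gene called over all genes was the laminin gene Lamb2 at -1.34. Of 28 mitotic genes 1 fell, or 5 when adjusted over the list alone (median -0.30, camera adjusted p 9.21e-05). This gene was the topoisomerase gene Top2a, which went from 0.16 ± 0.11 to -0.83 ± 0.06. Of 14 labyrinth genes only Epha4 fell over all genes, and 2 fell when adjusted over the list alone (median -0.19, camera adjusted p 0.00949). Of 25 invasion proteases 3 fell when adjusted over the list alone without a call over all genes (median -0.34, camera adjusted p 0.00206). The 15 FGF and ERK targets had a median of 0.43 without a member called (camera adjusted p 0.00949). Of 27 hypoxia and glycolysis genes Bnip3 rose by 1.81 and Gapdh fell by 1.38, with 6 up when adjusted over the list alone (median 0.19, camera adjusted p 0.0183).

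The 10 genes named in every comparison did not pass between T(Inv) and T(Diff). Cdh1 was lower by a log2 difference of -0.92 (adjusted p 0.0895), Map3k4 by -0.79 (adjusted p 0.0867) and Crebbp by -0.47 (adjusted p 0.274). Cdh1 and Map3k4 were called with slide as a random block (-1.00 and -0.85, adjusted p 0.0313 and 0.0284) and with duplicate arrays as a random block (adjusted p 0.0445 for both). Snai1 at -0.06, Snai2 at 0.17, Vim at -0.09, Ep300 at 0.09, Hdac6 at -0.12, Cdx2 at 0.40 and Eomes at -0.18 differed by less, and neither the EMT factor list (median 0.19, camera adjusted p 0.2) nor the mesenchymal list (median -0.04, camera adjusted p 0.991) was called. Within the stress kinase list of 19 genes 2 rose and 1 fell, or 4 fell when adjusted over the list alone (median 0.14, camera adjusted p 0.819). The MAP3K4 activator gene Gadd45g fell by 1.28, its relative Gadd45a rose by 0.99 and the JNK gene Mapk8 rose by 0.83 (adjusted p 0.0496). limma called 104 genes, 52 higher and 52 lower, of which 41 and 36 differed at least 2-fold. In 5516 genes (28.9%, against 10% by chance) the groups did not overlap. The count of calls is fragile: leaving out any of the 6 samples left 1 to 4 genes, with Thbd called each time, and quantile normalization left 27. The latter ended the calls of Emp1 (2.86, adjusted p 0.0873), Ccn2 (2.46), Notch3, Top2a, Gadd45g, Gadd45a, Mapk8, Bnip3 and Gapdh. With the feature of largest variance Mapk8 was at 0.32 (adjusted p 0.608), and Epha4 (-2.55), Notch3, Top2a, Gadd45g, Gadd45a, Bnip3 and Gapdh also lost their calls. Robust moderation ended those of Mapk8 (adjusted p 0.0525), Notch3 (0.051) and Bnip3 (0.0511), and duplicate arrays as a random block that of Gapdh (0.0579). With only the groups compared limma called 1 gene and with treat 2. With slide as a fixed block limma called 0 genes (2417 at an unadjusted p under 0.05), and within slide 1, which holds T(Inv) sample 3 and all T(Diff) samples, it called 1. With slide as a fixed block the differences are those within slide 1 and rest on T(Inv) sample 3 alone against the 3 T(Diff) samples. The medians were then -0.98 for basement membrane, -0.40 for mitotic, -0.28 for labyrinth, -0.51 for protease, 0.46 for FGF and ERK and 0.32 for hypoxia genes. The labyrinth, FGF and ERK and hypoxia lists lost their calls without T(Diff) sample 2 (medians -0.20, 0.38 and 0.25) and without T(Inv) sample 3 (medians -0.17, 0.42 and 0.13).

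The comparison of TS(KI4) with TS(WT) asks which genes change in undifferentiated TS cells when MAP3K4 is inactive. TS(KI4) and TS(WT) may also differ as cell lines. For every gene below, an effect of MAP3K4 cannot be separated from such a difference. Map3k4 RNA itself was at 0.26 in sample 1 and 0.25 in sample 2 (adjusted p 0.302), which checks nothing about the labels because an inactive allele is still transcribed. No change was called in the main TS cell factors, with Cdx2 at 0.06 ± 0.18 (n = 2, adjusted p 0.855), Eomes at -0.10 ± 0.24 (adjusted p 0.75) and 15 of 16 TS cell genes not called. Itm2a, a membrane protein gene on the X chromosome, had the highest change of the genes named, 6.40 ± 0.73, followed by the nuclear receptor gene Nr0b1 at 5.52 ± 0.35 and Fam111a, a protease gene, at 4.83 ± 0.08. The small GTPase gene Rhoa fell by 4.34 ± 0.07, and its neighbours Tcta and Nicn1 were at -3.22 ± 0.04 and -2.90 ± 0.57. Gadd45a rose by 2.07 ± 0.14 and Map2k6, a kinase gene of the p38 pathway, rose by 1.44 ± 0.12, within a stress kinase list of 19 genes of which 5 rose (6 when adjusted over the list alone) and 1 fell (median 0.23, camera adjusted p 0.17).

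**Figure D2:**
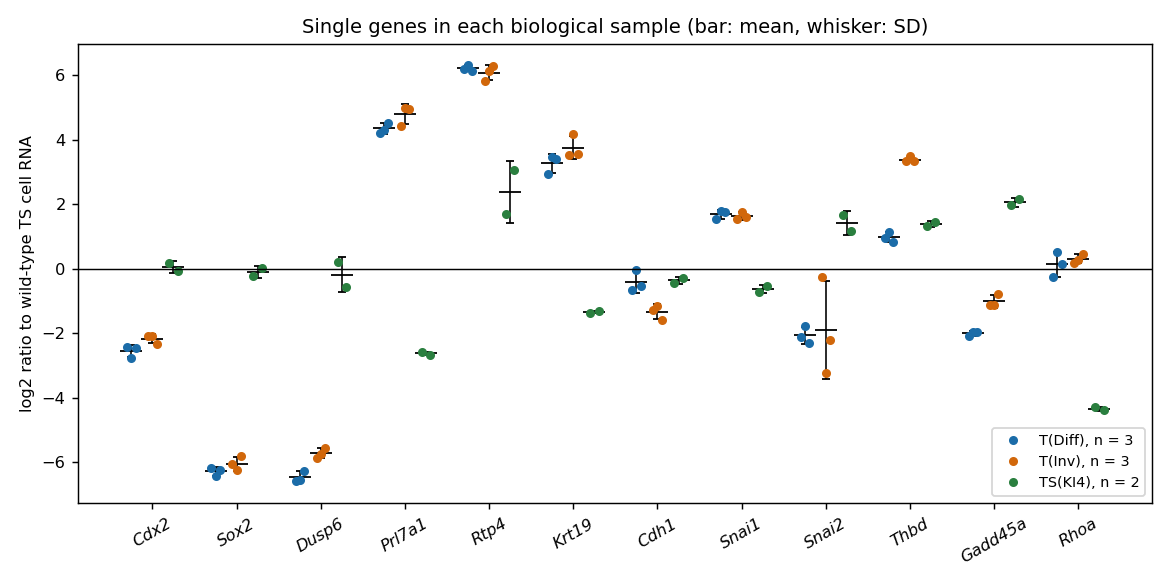
Log2 change against TS(WT) (vertical axis) of single genes in each sample, with the group mean and SD for T(Diff), T(Inv) and TS(KI4). Snai1 lies at 1.70, 1.63 and -0.62, and Snai2 at -2.06, -1.89 and 1.42.

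EMT-related genes went both ways in TS(KI4). Snai1 fell by 0.62 ± 0.13 (adjusted p 0.00934), Snai2 was at 1.42 ± 0.37 without passing (adjusted p 0.133), Twist1 rose by 1.11 ± 0.50 and Foxc2 and Twist2 fell by 1.80 ± 0.56 and 1.62 ± 0.74, all of them transcription factors of EMT. Snai2 was called after quantile normalization (1.63, adjusted p 0.0342), with slide as a random block (adjusted p 0.0421) and with only the groups compared (adjusted p 0.00693), and Snai1 was not called with treat (adjusted p 0.0756). Without TS(KI4) sample 1 the calls of Snai1 (-0.53, adjusted p 0.0973) and Twist1 (0.76) were lost. Of 14 EMT factors 4 rose and 3 fell (median 0.17, camera adjusted p 0.995). Outside chromosomes 1, 2, 8, X and Y, 2 of 7 EMT factors rose and 0 fell (median 0.44, camera adjusted p 0.219). The 3 that fell lie on the chromosomes left out, so this fit says nothing about their falls. Genes of chromosomes 1, 2 and 8 were lower in TS(KI4) as a whole, with medians of -0.18, -0.19 and -0.29 relative to the other autosomes. These shifts were smaller than the falls of Snai1, Foxc2 and Twist2. Of 30 mesenchymal genes 5 rose (6 when adjusted over the list alone) and 1 fell (median 0.17, camera adjusted p 0.386), among them the growth factor receptor gene Pdgfrb at 2.52 ± 0.15 and the crosslinking enzyme gene Loxl2 at 1.81 ± 0.03, which lost its call without sample 2 (1.79). Pdgfrb is also a marker of fibroblast feeder cells. Among 18 such markers 7 rose and 1 fell (median 0.26, camera adjusted p 0.0875, adjusted p = 0.49 with an estimated correlation). Without the genes of chromosomes 1, 2, 8, X and Y the camera adjusted p of these markers was 0.0443. Of 34 epithelial genes 8 fell and 4 rose (median -0.11, camera adjusted p 0.0754), with Krt7 at -1.61 ± 0.66 and Krt19 at -1.34 ± 0.04. Cdh1 was at -0.36 ± 0.10 and not called (adjusted p 0.225), but was called after quantile normalization, at -0.60 (adjusted p 0.017). Because that normalization widens the ratios of TS(KI4), calls gained with it are not separate support. Vim was at 0.30 ± 0.50 (adjusted p 0.508), and its 2 features differed, -0.71 and 1.31, the latter being that of largest variance and called (adjusted p 0.00332). Of 16 protease inhibitor genes 6 rose, and 1 fell when adjusted over the list alone (median 0.34, camera adjusted p 0.0718), with Timp2 at 2.27 ± 0.34. Among the enzymes of histone acetylation, Hdac6 rose by 0.99 ± 0.68 (adjusted p 0.012) but was not called without sample 2 (0.51, adjusted p 0.0924), while Crebbp at -0.14 ± 0.18 (adjusted p 0.721) and Ep300 at 0.06 ± 0.19 (adjusted p 0.883) were not called.

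Camera called 2 of the 30 lists in TS(KI4). Of 28 mitotic genes 10 fell (14 when adjusted over the list alone) and 1 rose (median -0.41, camera adjusted p 1.75e-05, adjusted p = 0.49 with an estimated correlation), among them Cenpf at -1.09 ± 0.51 (-0.73 and not called without sample 1) and the checkpoint kinase gene Bub1 at -1.03 ± 0.27. Of 18 cholesterol synthesis genes 6 fell, or 7 when adjusted over the list alone (median -0.54, camera adjusted p 1.81e-04, adjusted p = 0.537 with an estimated correlation). Without TS(KI4) sample 1 this list was no longer called (median -0.09, adjusted p 0.18). Both lists were also lower without the genes of chromosomes 1, 2, 8, X and Y, at medians of -0.32 and -0.41 (camera adjusted p 5.02e-04 and 0.00251). Fewer members were then called, with 4 of 21 mitotic genes lower and 1 higher, and 3 of 14 cholesterol synthesis genes lower. The changes in TS(KI4) differed by chromosome. Relative to the median of the other 16 autosomes, the median gene of chromosomes 1, 2 and 8 lay at -0.18, -0.19 and -0.29, against -0.04 to 0.07 on each of those 16 and 0.12 on the X. Xist, the RNA that silences an X chromosome, rose by 1.89 ± 0.41, and the Y-linked genes Uty, Eif2s3y and Uba1y fell by 2.52 ± 0.61, 2.72 ± 0.60 and 1.81 ± 0.04. Of the genes called and 2-fold changed, 92 on the X were higher and 8 lower, against 967 and 286 on the autosomes (odds ratio 3.40, two-sided Fisher exact p 2.23e-04). Against the autosomes other than 1, 2 and 8, a set chosen after their shift was seen, with 842 higher and 186 lower, the odds ratio was 2.54 (p 0.00821). The Fisher test counts genes, which are not independent replicates, so both p-values may be too small. limma called 3783 genes, 2321 higher and 1462 lower, of which 1061 and 299 changed at least 2-fold. Quantile normalization gave 7154 calls, with 1613 and 1102 at least 2-fold changed, and the count fell to 2185 without sample 1 and 1663 without sample 2, where the remaining sample is assumed to vary like the other groups.

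**Figure D3:**
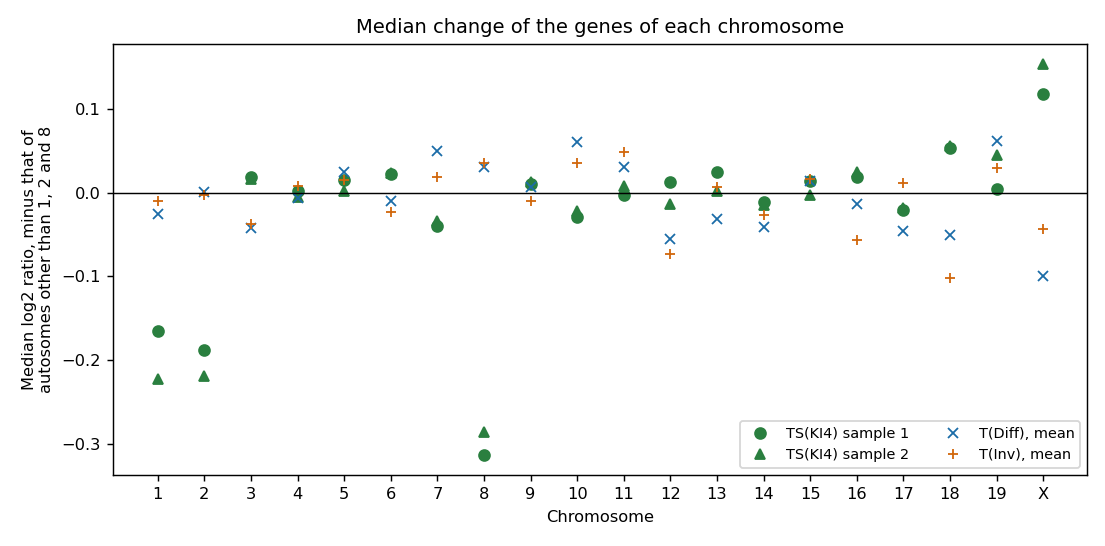
Median log2 change of the genes of each chromosome, minus that of the autosomes other than 1, 2 and 8 (vertical axis, log2 units; horizontal axis, chromosome), in T(Diff), T(Inv) and TS(KI4) against TS(WT). Chromosomes 1, 2 and 8 lie at -0.18, -0.19 and -0.29 in TS(KI4), and chromosome 8 at 0.03 and 0.04 in T(Diff) and T(Inv).

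The changes in TS(KI4) were set against those of T(Diff) and T(Inv) to ask whether inactive MAP3K4 moves TS cells towards either state. With T(Diff), TS(KI4) shared 628 higher and 621 lower genes (618 and 412 for independent lists, 321 in the simulation of both directions), and 1552 genes were called in opposite directions (1043 for independent lists). With T(Inv) it shared 615 higher and 620 lower genes (606 and 403 for independent lists, 316 in the simulation), and 1561 went in opposite directions (1022 for independent lists). Part of any excess in the same direction may come from the shared reference. Across genes the changes correlated at -0.09 with T(Diff) (simulated 0.708) and at -0.09 with T(Inv) (simulated 0.706), with covariances of -0.051 and -0.049 (simulated 0.107 for both).

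Set directly against T(Diff), TS(KI4) had higher Cdx2 by 2.62 (SE 0.18, adjusted p 2.64e-05) and Snai2 by 3.48 (SE 0.74, adjusted p 0.00579), and lower Snai1, at -2.32 (SE 0.16, adjusted p 2.62e-05), and Eomes, at -0.84 (adjusted p 0.00754). Against T(Inv), Cdx2 was higher by 2.22, Snai2 by 3.31 (adjusted p 0.00728), Map3k4 by 0.80 (adjusted p 0.00978) and Cdh1 by 0.98 (adjusted p 0.00902), and Snai1 at -2.26, Eomes at -0.67 (adjusted p 0.0222) and Ep300 at -0.61 (adjusted p 0.0442) were lower. Without TS(KI4) sample 1 the calls of Snai2 against both groups were lost (3.22 and 3.05), and without sample 2 those of Eomes against both (-0.68 and -0.50) and of Cdh1 against T(Inv) (0.91). Those of Ep300 and Eomes against T(Inv) were also lost without T(Inv) sample 1 or 2, and that of Ep300 without either TS(KI4) sample (-0.48 and -0.74). Cdh1 against T(Inv) lost its call after quantile normalization (0.45, adjusted p 0.105). Map3k4 against T(Inv) lost its call with the feature of largest variance (0.14, adjusted p 0.839) and with the replicate block (0.70, adjusted p 0.0587). The replicate block also ended the calls of Eomes against both groups (-0.86 and -0.76) and of Ep300 against T(Inv) (-0.72, adjusted p 0.085). The latter was also lost with duplicate arrays as a random block (adjusted p 0.143), after quantile normalization (0.0543), with only the groups compared (0.0592) and with treat (0.158), and that of Eomes against T(Inv) with treat (0.0889).

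Against T(Diff), Cdh1 at 0.06 (adjusted p 0.873), Map3k4 at 0.01 (adjusted p 0.967), Crebbp at -0.55 (adjusted p 0.0984), Ep300 at -0.52 (adjusted p 0.0748) and Hdac6 at 0.47 (adjusted p 0.194) were not called. Nor were Crebbp at -0.08 (adjusted p 0.821) and Hdac6 at 0.59 (adjusted p 0.112) against T(Inv). Hdac6 was called against both after quantile normalization (0.81 and 0.90) and without TS(KI4) sample 1 (0.95 and 1.07). With the feature of largest variance Map3k4, Crebbp and Ep300 were called against T(Diff) (-1.58, -1.05 and -1.69), and Crebbp was also called without T(Diff) sample 1 (-0.77). Vim at 0.83 from T(Diff) (adjusted p 0.0739) and 0.92 from T(Inv) (adjusted p 0.0527) missed the threshold. With the feature of largest variance it was called against both, at 2.82 (adjusted p 8.17e-05) and 2.27 (adjusted p 1.85e-04). Against T(Inv) it was also called with the replicate block (1.08, adjusted p 0.0261), with only the groups compared (adjusted p 0.0443) and without T(Inv) sample 3 (1.08) or TS(KI4) sample 1 (1.27).

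FGF and ERK targets were higher in TS(KI4) than in T(Diff), with 12 of 15 up and 1 down (median 2.41, camera adjusted p 1.64e-04, adjusted p = 0.583 with an estimated correlation), and than in T(Inv), with 12 up and 2 down (median 1.69, camera adjusted p 0.00157, adjusted p = 0.736 with an estimated correlation). Giant cell genes were lower, with 10 of 18 down and 2 up against T(Diff) (median -1.06, camera adjusted p 9.40e-04, adjusted p = 0.576 with an estimated correlation) and 11 down and 1 up against T(Inv) (median -1.59, camera adjusted p 7.10e-04, adjusted p = 0.602 with an estimated correlation). Labyrinth genes were lower, with 12 of 14 down and 1 up against T(Diff) (median -1.52, camera adjusted p 2.50e-04, adjusted p = 0.576 with an estimated correlation) and 8 down and 1 up against T(Inv) (median -0.92, camera adjusted p 0.0218, adjusted p = 0.736 with an estimated correlation). Epithelial genes were lower, with 20 of 34 down (21 when adjusted over the list alone) and 3 up against T(Diff) (median -0.95, camera adjusted p 2.62e-05, adjusted p = 0.583 with an estimated correlation). Against T(Inv) 19 were down and 5 up, or 20 and 6 when adjusted over the list alone (median -0.76, camera adjusted p 0.00215, adjusted p = 0.736 with an estimated correlation). Interferon response genes were lower, with 19 of 24 down and 2 up against either group (medians -2.14 and -1.86, camera adjusted p 2.86e-07 and 3.15e-06, adjusted p = 0.576 and 0.602 with an estimated correlation). Of 18 immediate early and heat shock genes 9 were lower and 2 higher than in T(Diff), or 11 and 3 when adjusted over the list alone (median -0.65, camera adjusted p 0.0341, adjusted p = 0.716 with an estimated correlation). Against T(Inv) 10 were lower and 4 higher (median -0.79, camera adjusted p 0.0236, adjusted p = 0.8 with an estimated correlation). Imprinted genes were lower than in T(Diff), with 9 of 22 down and 2 up, or 3 up when adjusted over the list alone (median -0.60, camera adjusted p 0.0341, adjusted p = 0.583 with an estimated correlation). Pluripotent cell markers were higher, with 7 of 15 up and 1 down (median 0.94, camera adjusted p 0.0278, adjusted p = 0.583 with an estimated correlation). Against T(Inv) the medians of these 2 lists were -0.59 (10 down and 4 up, or 11 down when adjusted over the list alone) and 0.75 (6 up and 1 down), without a call (camera adjusted p 0.103 and 0.0983). Without T(Diff) sample 2 the calls of imprinted, immediate early and pluripotent genes against T(Diff) were lost (medians -0.51, -0.68 and 0.58). Immediate early genes against both groups (medians -0.56 and -0.54) and pluripotent markers (0.53) also lost theirs without TS(KI4) sample 2, and imprinted genes without TS(KI4) sample 1 (-0.37). The labyrinth call against T(Inv) was lost after quantile normalization (median -0.96). limma called 8379 genes against T(Diff), 4700 higher and 3679 lower, and 8355 against T(Inv), 4656 higher and 3699 lower, of which 5299 and 5258 differed at least 2-fold. TS(KI4) shared no slide with either group, so an effect of slide or of a different reference RNA cannot be separated from these differences.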

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

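The tests of Xist and the Y-linked genes were chosen after their result had been seen, as were the fits without chromosomes 1, 2, 8, X and Y, those of genes whose features share a sign and the test of feature pairs among accessions with 2 or 3 features.

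TS(KI4) and T(Inv) were each set against RNA of wild-type TS cells, and the direct comparison of their effects found differences between the groups. In 1561 genes both were called in opposite directions, against 1022 for independent lists. Each had a called difference between TS(KI4) and T(Inv), which opposite calls make likely in advance, so it adds no separate support. The median difference, TS(KI4) minus T(Inv), was -1.587 log2 for trophoblast giant cell genes, -0.761 for epithelial junction and identity genes and -0.79 for immediate early and heat shock genes, and it was -2.256 for Snai1. Snai1 was above 0 in all T(Inv) samples and below 0 in both TS(KI4) samples. The pairs of groups differ in differentiation and slide as well as in MAP3K4, so these differences cannot be read as effects of MAP3K4 alone.

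Features without a single gene symbol, which the gene-level comparisons leave out, also held signal. Of 11567 such features, 2057 were called and 2-fold changed in T(Diff), 2033 in T(Inv) and 542 in TS(KI4), which is 17.8%, 17.6% and 4.69% of them, against 28.2%, 28.1% and 7.19% of the features with a symbol.

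Xist was higher in TS(KI4) by 1.89 log2 and 3 Y-linked genes (Uty, Eif2s3y and Uba1y) were lower, each below 0 on all 4 arrays. Fibroblast feeder RNA in the wild-type reference, which would lower feeder markers in TS(KI4), is argued against by their median of 0.26, with 7 of 18 higher and 1 lower. Eif2s3y and Uba1y were also lower in T(Diff), at -1.38 and -1.07, where Uty was at 0.29. The other 10 of 13 Y-linked genes were not called in TS(KI4) (-0.34 to 0.34), and Kdm5d, at 0.34, was below 0 on none of the 4 arrays. Without intensities it is not known which of them were detected. The 3 lower Y-linked genes could come from TS(KI4) being a line with other sex chromosomes than the wild-type line, for example from an embryo of the other sex or after loss of the Y. The sex of the lines is not given in the labels, so sex differences and the effect of MAP3K4 cannot be separated for these genes. Nor can other differences between the lines be separated from the effect of MAP3K4 for any gene.

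Genes of chromosomes 1, 2 and 8 were lower in TS(KI4), with chromosome 8 lowest at -0.292. All shifts given here are medians relative to the autosomes other than 1, 2 and 8, and -0.292 was taken after averaging each gene over arrays and samples. A fault of 1 slide or array is argued against by chromosome 8, whose smallest shift over the 4 single arrays was -0.312, and a few strongly changed genes or a single block by its 5 stretches, whose smallest shift was -0.195. If all slides carried the same wild-type RNA, a reference that differed from the cells behind T(Diff) and T(Inv) would shift chromosome 8 there. The larger shift in those groups was 0.036. Whether the RNA was the same is not known, and TS(KI4) shared no slide with these groups. Another wild-type RNA on the TS(KI4) slides thus stays open. A gain shared by the wild-type reference and the T cells, or a loss in part or all of the TS(KI4) cells, may be the source and stays open, as does an effect of MAP3K4 itself. Without chromosomes 1, 2, 8, X and Y, 2569 genes were called in TS(KI4), 1882 higher and 687 lower.

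In T(Diff) and T(Inv), 1269 and 1367 of 8343 genes with several features (15.2% and 16.4%) had features called in opposite directions, against 30 (0.36%) in TS(KI4). Of the called pairs of features in T(Diff), 9.48% were opposite with the same accession and 32.9% with different accessions, and in T(Inv) 10.6% and 37.9%. Different transcripts of a gene, which predict such a gap of more than a factor of 2, thus could be a cause. Among accessions with 2 or 3 features 20.9% of the same-accession pairs in T(Diff) were opposite, a gap below that factor, so how much they explain stays open. A dye effect shared by all arrays is argued against by the correlation of the features' deviations between T(Diff) and TS(KI4), 0.044, while between T(Diff) and T(Inv) it was 0.886. Signal near background with a bias that T(Diff) and T(Inv) share, or probes that bind other transcripts of differentiated cells, could give such features, and without intensities this stays open. With only genes whose features share a sign, 9048 genes were called in T(Diff) and 8771 in T(Inv).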

How the results depend on the processing

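The settings without chromosomes 1, 2, 8, X and Y, with only genes whose features share a sign and with the X set against the autosomes other than 1, 2 and 8 were chosen after the data were seen. Of the values of named genes under the alternatives, 5560 stayed called or stayed uncalled, 395 lost a call and 41 gained one. A further 2, called in the main fit, reversed. Changes of sign in genes called in neither fit were not counted as reversals. For single lists 358 kept and 70 lost the call. Both reversals came with the feature of largest variance, Pecam1 in T(Inv) (-0.009) and Kdr in TS(KI4) (-1.202), and neither was then called. For the rest of this part the cause was not tested, with the following exceptions. Fewer samples or genes, a stricter test, a finer block or the common distribution set by quantile normalization can itself be the change.

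The count for T(Inv) against T(Diff), 104, became 27 after quantile normalization, 31 with the feature of largest variance, 1 with only the groups compared, 2 with treat, 307 with duplicate arrays as a random block and 606 with slide as a random block. Slide as a fixed block gave 0 in limma (2417 at an unadjusted p under 0.05), and the value within the slide that holds both groups was 1. For TS(KI4) the count, 3783, became 7154 after quantile normalization, 5824 with slide as a random block and 1889 with treat. Overlaps among genes also 2-fold changed were 3457 for T(Diff) and T(Inv), 228 for T(Diff) and TS(KI4) and 208 for T(Inv) and TS(KI4). The overlaps of TS(KI4) with T(Diff) and T(Inv) were 2120 and 2135 after quantile normalization, 483 and 449 with treat and 821 and 810 without chromosomes 1, 2, 8, X and Y, and with slide as a random block that with T(Inv) was 1908. The correlation of TS(KI4) with T(Diff) was -0.071 after quantile normalization, -0.127 with the feature of largest variance and -0.111 without those chromosomes, and that with T(Inv) was -0.124 with the feature of largest variance.

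Leaving out a sample gave 1 to 4 calls in T(Inv) against T(Diff) and 1663 to 2185 in TS(KI4), where the lone sample is assumed to vary like the other groups. It gave overlaps of TS(KI4) with T(Diff) of 594 to 1349 and with T(Inv) of 569 to 1009, and correlations of -0.101 to -0.067 and -0.111 to -0.053. Lists called ranged from 3 to 9 in T(Inv) against T(Diff), 5 to 8 in TS(KI4) against T(Diff) and 3 to 7 in TS(KI4). Camera with an estimated correlation called 0 lists in each of the 6 comparisons, where 2, 1, 1, 0, 1 and 2 of 30 had an unadjusted p under 0.05. Its adjusted p could also rise where the estimated correlation lay below the preset 0.01. Protease inhibitors in TS(KI4), with an estimated correlation of -0.017, went from a camera adjusted p of 0.0718 to 0.49. For other lists the estimate lay far above the preset. It was 0.60 for cholesterol synthesis, 0.49 for FGF and ERK, 0.33 for basement membrane, 0.28 for epithelial and 0.26 for mitotic genes. For these lists the preset may understate the variance, so their camera p-values at the preset may be too small. fry, which does not compare a list with other genes, called 24 lists in T(Diff), 25 in T(Inv), 15 in TS(KI4), 0 in T(Inv) against T(Diff) (8 at an unadjusted p under 0.05), and 21 in TS(KI4) against T(Diff) and 21 against T(Inv). Without those chromosomes camera called 6 lists in TS(KI4), the other 4 being epithelial (lower), protease inhibitor (higher), endocycle (lower) and feeder genes (higher). Each of these 4 was at a camera adjusted p of 0.0443. An estimated correlation was not used in this setting, and on all genes it gave them adjusted p = 0.746, 0.49, 0.49 and 0.49.

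The replicate numbers were tested as pairs. Deviations of same-numbered T(Diff) and T(Inv) samples correlated at 0.023, 0.086 and 0.07, against -0.082 to 0.036 for different numbers. With 3 samples a group, values this small cannot tell whether the numbers pair the samples. With the replicate block limma called 0 genes in T(Inv) against T(Diff) (3524 at an unadjusted p under 0.05), 5722 in TS(KI4) against T(Diff) and 7224 against T(Inv).

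Centring and robust moderation left every count of genes within 1.5 times its value. With no missing value, the alternatives on missing values were not run. Without intensities, signal over background could not be used to limit the genes.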

Other observations

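The gene families, the neighbours of Rhoa and the test of the genes called higher in T(Inv) than in T(Diff) were chosen after their result was seen, and the germline list after 4 of its genes were seen among the highest.

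Germline genes were among the highest in TS(KI4): Ddx4 at 3.94 ± 0.12, Tdrd12 at 3.88 ± 0.08, Gtf2a1l at 3.81 ± 0.08 and Dnajb3 at 3.77 ± 0.06 (SD, n = 2). In a list of 27 other germline genes 15 rose and 1 fell, with a median of 1.086 (camera p 7.73e-07, 0.014 with an estimated correlation), among them the meiotic genes Sycp3 at 3.44 and Syce1 at 3.17. Outside chromosomes 1, 2, 8, X and Y, 12 of 21 rose and 1 fell. In T(Diff) 12 of the 27 fell and 2 rose (median -0.50). Inactive MAP3K4 may thus go with a rise of germline genes, or the line may have drifted in culture, which these data do not separate.

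Some of the 7 gene families looked at moved together, without a test of the families. Of 20 Prl genes 11 rose and 1 fell in T(Diff), 10 rose and 1 fell in T(Inv), and 5 fell and 1 rose in TS(KI4). All 6 Serpinb9 relatives rose in T(Diff) and in T(Inv), and 3 fell in TS(KI4). Of 17 X-linked Tceal, Bex, Armcx and Gprasp genes 12 rose in TS(KI4) (median 1.45), while 8 fell and 1 rose in T(Diff). Of 10 Gbp genes 8 rose in T(Diff) and of 6 Ifit genes 4. Others did not move together: of 14 Ceacam genes 5 rose and 2 fell in T(Diff) and 3 rose and 3 fell in T(Inv), and of 8 Psg genes 0 were called in T(Diff) and 1 fell in T(Inv). Probes of these families can bind more than 1 member.

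Rhoa and its neighbours Tcta and Nicn1 had among the lowest values in TS(KI4), and of the 24 nearest measured genes around Rhoa 14 were called lower and 3 higher. Of all 19087 genes, 1462 were called lower and 2321 higher. In T(Diff), Rhoa, Tcta and Nicn1 were at 0.14, 1.37 and 0.20, so their fall was not shared with T(Diff). In TS(KI4), 145 neighbouring pairs of genes were called and 2-fold changed in the same direction, against a mean of 63.5 and at most 87 in 1000 shuffles of gene order. An excess of such pairs over the whole genome is not specific to TS(KI4). T(Diff) had 782 such pairs against a mean of 532 and at most 590, and T(Inv) had 727 against 511 and at most 576. These counts cover all genes and do not bear on the genes around Rhoa.

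Whether T(Inv) departs from T(Diff) as TS(KI4) departs from TS(WT) was tested across genes, and r was 0.006 (0.00975 without chromosomes 1, 2, 8, X and Y), which argues against a shared direction over all genes. Of the 52 genes called higher in T(Inv) than in T(Diff), 20 were higher and 8 lower in TS(KI4) (camera p 0.0055, 0.0841 with an estimated correlation), so a shared direction among these genes stays open. Of the 52 lower genes 9 were higher and 9 lower.

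The 6 T(Diff) and T(Inv) samples can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split called 104 genes, and the highest of the others called 0 in limma (625 to 1601 at an unadjusted p under 0.05), so 1 split, the real one, gave as many.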
